A study of Mus musculus with 5 samples.

How the data were processed

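The series gave 2 droplet libraries of non-cardiomyocyte heart cells, 1 from mice of 2 months and 1 from mice of 18 months, and 1 pooled library of CD44-high T cells from the lymph nodes that drain the heart. The pool mixed ages 2, 6, 12 and 18 months, told apart by 8 hashtag antibodies, and came with T cell receptor contigs. No source used here names the age of a hashtag, so the hashtag samples stayed unassigned and were never read as ages. The separate sample of hashtag antibody reads was not analysed here, since the hashtag counts came with the lymph node gene matrix.

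The deposited gene matrices hold counts: UMIs per gene and cell barcode, unscaled, written by Cell Ranger 3.1.0 per the file headers. Genome names mm10 and GRCm38 come from the submitters' processing notes. The receptor files also hold counts per the file headers, as UMIs per contig and cell barcodes per clonotype. The authors' deposited text names Seurat 4.0.6 for their own filters and clusters, and for the heart a filter of 200 genes, 8% mitochondrial UMIs and 15000 UMIs per cell, which was run here as an alternative, as was their lymph node filter.

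Everything below was computed from the counts with Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, Scanpy 1.11.5, igraph 0.11.9, leidenalg 0.10.2 and Matplotlib 3.10.9. Heart cells were kept with at least 200 genes and at most 15% mitochondrial UMIs. The 2-month library went from 12235 barcodes to 11388, and the 18-month library from 8844 to 8035. Scrublet, run per library at an expected doublet rate of 8%, then took out 493 and 228 cells as doublets. This left 10895 cells with a median of 8033 UMIs at 2 months and 7807 cells with a median of 4368 UMIs at 18 months. In all, the kept cells held 102421485 and 53528180 UMIs.

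Both heart libraries were clustered together by the Leiden method at resolution 1, with 2000 variable genes, 30 principal components and 15 neighbours. Genes of the interferon and MHC lists, mitochondrial, ribosomal, haemoglobin and receptor variable genes, Xist and Y-linked genes did not enter the clustering. The 41 clusters were named by marker genes fixed before the data were examined. A cluster stayed unnamed when it had fewer than 3 of its own markers, when markers of another class led its top 10 genes, when it carried markers of another lineage, or when at least 5 of the top genes were cell cycle genes. These limits were not part of the plan fixed beforehand. Unnamed clusters (8 of 41) held 13.2% of 2-month and 10.2% of 18-month cells and entered no class.

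For each class with at least 50 cells in each library, UMIs were summed over cells and scaled to CPM of the class total. The log2 ratio, always 18 over 2 months, carries the exact conditional binomial 95% interval, and shares of cells carry Clopper-Pearson intervals. With 1 library per age, cells are not replicates, so no p value between ages was computed for the heart. Counts of genes past the fold rule and ranks among random lists describe these libraries alone. Free RNA was estimated per class as the median, over markers of other lineages with at least 20 expected UMIs, of their share in the class over their share in the whole library. This estimate was 7.43% and 6.87% of UMIs in vascular endothelial cells, 8.10% and 5.68% in fibroblasts and 5.54% and 6.82% in T cells.

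Gene lists (20) were fixed beforehand: interferon gamma (IFN-γ) response, MHC class I and antigen processing, MHC class II, type I interferon-stimulated genes, mitochondrially encoded and nuclear oxidative phosphorylation genes, glycolysis, fatty acid oxidation, dissociation stress, inflammatory cytokines, extracellular matrix, complement, senescence and CDK inhibitors, cell cycle, T cell effector, T cell naive, T cell exhaustion and checkpoint, haemoglobin, cardiomyocyte genes, and ribosomal proteins. A member was measured with at least 20 UMIs over both libraries. The list value is the median log2 ratio of its measured members, with an interval from 1000 Poisson draws of the sums. It was ranked as a percentile among 10000 random lists of the same size, matched in 20 bins of mean expression. Members counted as higher or lower had a ratio of at least 1.5-fold and an interval that left out 0.

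Genes named in the text followed a rule fixed beforehand: per class, the 5 highest and 5 lowest ratios among genes with at least 50 CPM in 1 library, at least 50 UMIs in all and an interval beyond 1.5-fold, without mitochondrial, ribosomal, receptor variable, haemoglobin and unnamed genes. Interferon, MHC and T cell genes chosen by name were added to it in every class, though the text does not print all of them. After the values were seen, Xist and Y-linked genes were left out, and so were genes with an estimated background of 50% or more of their UMIs. Further genes by rank were then added in the larger classes, where background was under 25% and the 5 richest cells held under 50% of the UMIs. Members of lists named in the text beyond these were also chosen after their values were seen.

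In the lymph node library, 12804 of 13016 barcodes had at least 200 genes and at most 10% mitochondrial UMIs. A cell was assigned to a hashtag with at least 10 UMIs and 3 times the second hashtag. This left out 57 cells with none and 2555 with more than 1 (20.0%), which removed doublets between hashtags. About 408 doublets within a hashtag (4.00%) were expected to remain among the 10192 assigned cells, which had a median of 2744.5 UMIs. Clusters (31) were made as for the heart and named by similar limits. Here a name also needed at least 1 own marker among the top 10 genes, and cycling cells were a named class. Unnamed clusters held 18.1% of cells.

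Clonotypes are the deposited identifiers, in cells with a productive TRB contig. These joined to 6974 assigned cells (68.4%). Clonality measures were thinned to 549 cells with a receptor per hashtag, the smallest number, as means of 1000 draws. Cells of clonotypes with at least 2 cells (expanded) were compared with cells of clonotypes of 1 cell (single) by the same sums, ratios and lists, over all cells and per hashtag. The ratios and list medians per hashtag were tested against 0 with an exact 2-sided sign-flip permutation test of their mean, for lists (16) and genes (21) measured in at least 6 hashtags, with Benjamini-Hochberg correction in each set. With 8 hashtags its smallest p is 0.00781. It was planned, but run after the values had been seen, and takes hashtags as separate samples, whose animals the sources used here do not name. Hashtags were not compared with each other by a test.

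The steps were tested on simulated data, drawn with counting noise only from the summed profiles of both sides, in which 200 genes were changed 1.5-, 2- or 4-fold. At 1.5-fold, 47.8% of the changed genes passed the fold and interval rule for list members in endothelial cells, 32.8% in fibroblasts, 40.6% in T cells and 44.8% in the lymph node comparison. At 2-fold these were 90.6%, 87.5%, 79.7% and 86.4%, and none was called in the wrong direction. Of unchanged genes, 1.09%, 1.19%, 2.03% and 0.98% were called. All 50 simulated lists of 33 members with a true log2 change of 0.32 were found in each comparison, and 4% of unchanged lists (0% in the lymph node) fell outside.

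Alternatives covered the filter on cells, doublets, cluster resolution, the genes used for clustering, TMM and median-of-ratios scaling, thinning to 1000 UMIs per cell, equal weight per cell, the total used for CPM and the minimum for list members. For the lymph node they covered the hashtag rule, the clonotype definition, the size that counts as expanded and subsets of cells. Clonotypes by TRB sequence were used for the clonality measures only, not for the ratios of expanded over single cells. Others were added after the data were seen: background subtraction, cells split by Xist and Y-linked transcripts, pairs of heart hashtags, cells without a hashtag, equal cluster or hashtag weights, T cells with a Cd3 UMI, the authors' filter, and in the lymph node leaving out hashtag 7 or B and myeloid clusters, type 1 clusters alone and other scaling. Equal cluster weights in the heart gave a cluster the same weight in both libraries, by its cells in both. Clusters with few cells in 1 library were left out there.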

Results

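The 2 heart libraries held 10895 cells at 2 months and 7807 cells at 18 months. All heart values below carry counting error only, and no replicate check was possible with 1 library per age. The lymph node library held 10192 T-cell-enriched cells in 8 hashtag samples of unnamed ages. Pairs of heart values are given as 2 months and then 18 months, with the log2 ratio and, where shown, its 95% interval after them.

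Fibroblasts made up 21.7% (20.9 to 22.4) of 2-month cells and 5.76% (5.26 to 6.30) of 18-month cells, a log2 ratio of -1.91 (-2.06 to -1.76). Vascular endothelial cells made up 24.8% (24.0 to 25.6) of 2-month cells and 29.3% (28.3 to 30.3) of 18-month cells, a log2 ratio of 0.24 (0.16 to 0.32). Neutrophils, short-lived phagocytes of the blood, made up 1.92% (1.67 to 2.19) of 2-month cells and 11.7% (10.98 to 12.4) of 18-month cells, a log2 ratio of 2.61 (2.39 to 2.83). Monocytes (0.578% and 3.97%, log2 ratio 2.78), macrophages (4.88% and 8.34%, log2 ratio 0.77), T cells (2.74% and 4.41%, log2 ratio 0.69), NK cells (0.147% and 0.781%, log2 ratio 2.41), B cells (8.63% and 12.7%, log2 ratio 0.56) and ILC2 (0.734% and 1.38%, log2 ratio 0.91) also had higher shares in the 18-month library, and dendritic cells differed little (2.82% and 3.46%, log2 ratio 0.30). Smooth muscle cells (7.06% and 1.91%, log2 ratio -1.89), pericytes (1.88% and 0.653%, log2 ratio -1.53), glial cells (0.532% and 0.179%, log2 ratio -1.57), epicardial cells (0.376% and 0.0512%, log2 ratio -2.88), plasma cells (0.441% and 0.0640%, log2 ratio -2.78) and the remaining cardiomyocytes (6.29% and 1.82%, log2 ratio -1.79) had lower shares. Endocardial cells, 1 cluster in which 6 of 142 and 82 of 228 cells had the marker Npr3, were higher (1.30% and 2.92%, log2 ratio 1.16), 1.16 to 2.33 over the settings, as were erythroid cells (0.0826% and 0.436%, log2 ratio 2.40). All leukocyte classes together came to 22.9% and 46.8%. How many stained, sorted or mixed cells of each kind entered a library is not given in the sources used here, so shares were also taken within each side. Among leukocytes alone, neutrophils were 8.38% and 24.9%, monocytes 2.53% and 8.48%, B cells 37.7% and 27.2%, macrophages 21.3% and 17.8% and T cells 12.0% and 9.41%. Among the other named classes, endothelial cells were 38.8% and 68.8%, fibroblasts 33.9% and 13.5% and smooth muscle cells 11.1% and 4.48%. An unnamed cluster led by Pi16, Mfap5 and Mfap4, genes of adventitial fibroblasts, held a further 7.77% and 1.74% of cells. The endothelial share ratio was 0.08 under the stricter filter and 0.05 under the authors' filter, so the small endothelial difference depended on the filter.

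**Figure D1:**
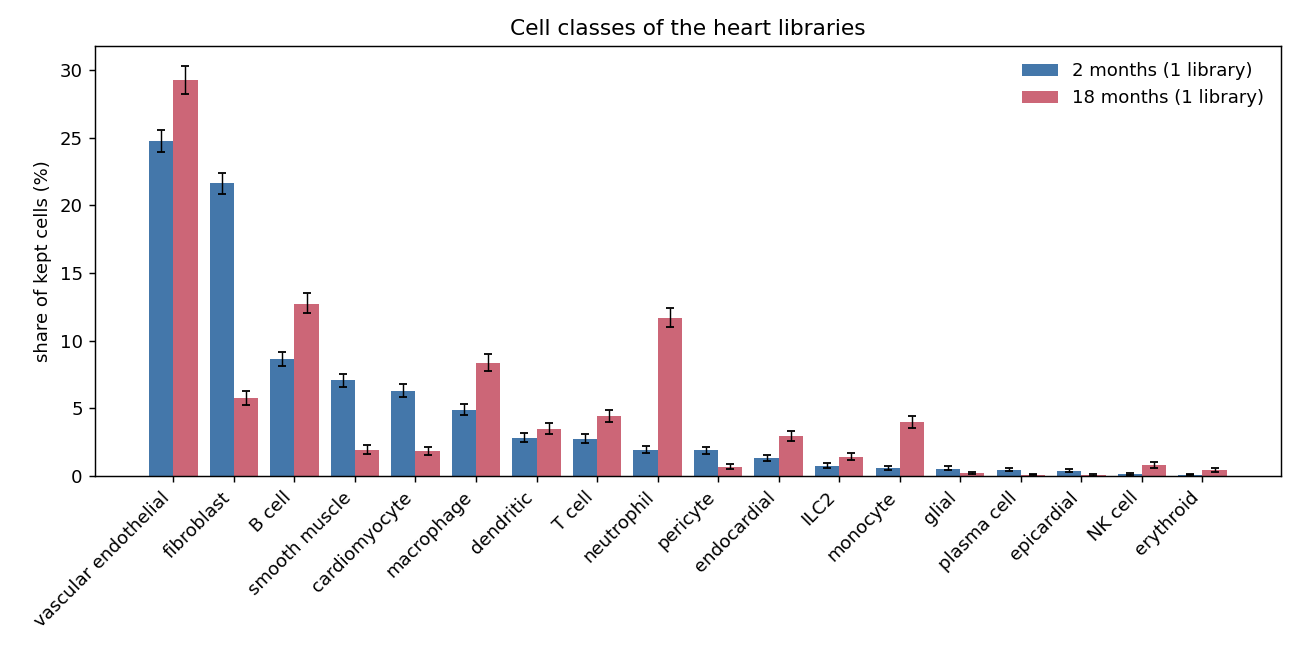
Percent of kept cells in each of 18 heart classes in the 2-month and 18-month libraries, with 95% Clopper-Pearson intervals (counting error only). Fibroblasts, smooth muscle cells and pericytes had lower shares, and neutrophils and monocytes higher shares, in the 18-month library.

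The IFN-γ response list was higher in fibroblasts of the 18-month library and lower in endothelial cells. Its median log2 ratio was 0.35 (0.21 to 0.40) in fibroblasts over 33 members, above all 10000 matched random lists. In vascular endothelial cells it was -0.21 (-0.27 to -0.12) over 36 members, below every random list. Smooth muscle cells (0.38, 0.14 to 0.56, 18 members), monocytes (0.27, 0.10 to 0.40, 28 members) and neutrophils (0.26, 0.03 to 0.41, 26 members) also had higher medians than at least 99.25% of random lists. Endocardial cells (-0.20, -0.39 to -0.03, 25 members), macrophages (0.04, -0.03 to 0.19), T cells (0.14, 0.00 to 0.32), dendritic cells (0.09), cardiomyocytes (0.09, 11 members), pericytes (0.11) and ILC2 (0.02) lay within the range of random lists. In B cells the median of 0.18 (0.02 to 0.25) sat beside a random median of 0.21, since most B cell genes had higher CPM at 18 months, and TMM scaling moved it to -0.06. With cells thinned to 1000 UMIs once, the neutrophil median turned to -0.11 and the fibroblast median was 0.06, against 0.39 over 20 thinnings, and it was 0.07 in fibroblasts with Y-linked UMIs and without Xist. Smooth muscle medians ran 0.005 to 0.77 and monocyte medians 0.03 to 0.58 over the settings, so both came close to 0 in places. Over 13 classes, 55 of 333 measured members were higher and 27 were lower by the fold rule.

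**Figure D2:**
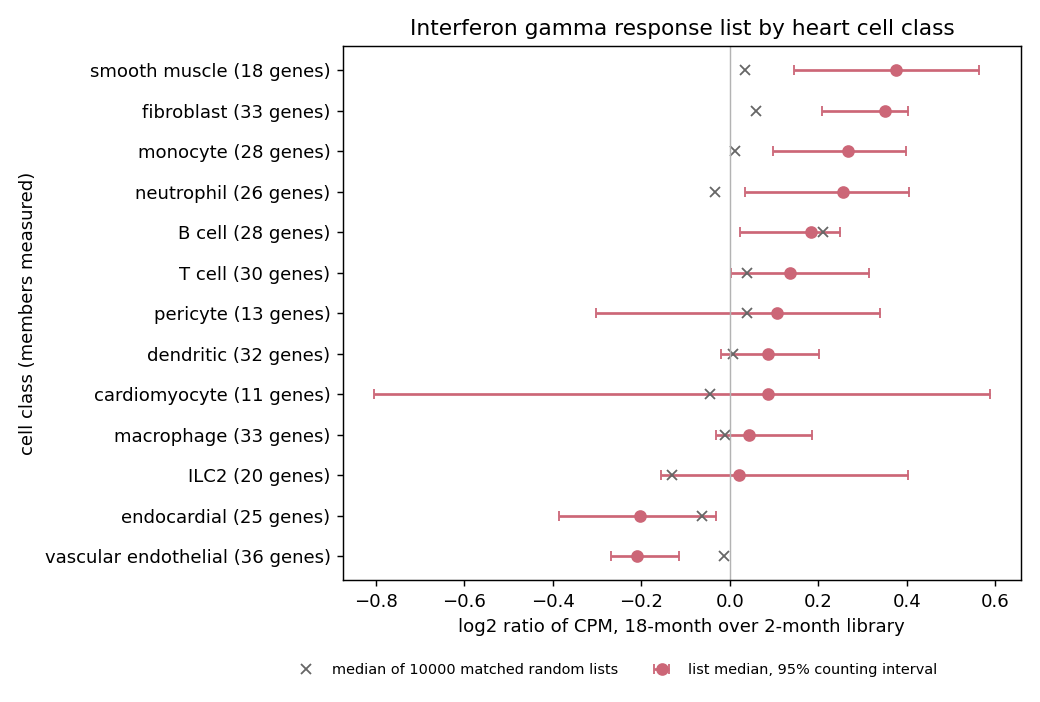
Median log2 ratio (18 over 2 months) of the IFN-γ response list in 13 heart classes, with 95% counting intervals, and crosses for the median of 10000 matched random lists. Fibroblasts and smooth muscle cells lie above, and endothelial cells below, their random lists.

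In fibroblasts (2359 and 450 cells), the MHC class I list median was higher in the 18-month library, with 2 of 22 members past the 1.5-fold rule, and the matrix list median lower. Below 1.5-fold, H2-K1 and H2-D1, classical MHC class I heavy chains, stood at 415 and 605 CPM (0.54, 0.48 to 0.60) and 628 and 874 CPM (0.48, 0.43 to 0.52). The class I partner B2m was at 684 and 834 CPM (0.29, 0.24 to 0.33). Immunoproteasome subunits Psmb9 (27.2 and 37.3 CPM, 0.46) and Psmb8 (85.7 and 114 CPM, 0.41) followed, with Gbp2 (47.0 and 58.0 CPM, 0.30), Bst2 (155 and 197 CPM, 0.34), Isg15 (64.7 and 81.1 CPM, 0.32) and the receptor chain Ifngr1 (199.7 and 232 CPM, 0.22). Over the settings, ratios ran -0.89 to 0.60 for Psmb9, -0.06 to 0.49 for Psmb8, -0.10 to 0.61 for Gbp2, -0.43 to 1.55 for Isg15 and -0.01 to 0.48 for Ifngr1. Irf1, an interferon-induced transcription factor, went the other way at 124 and 72.5 CPM (-0.77, -0.93 to -0.62). The interferon-inducible p200 family genes Ifi207 at 38.5 and 122 CPM (1.66, 1.52 to 1.81) and Ifi205 at 54.7 and 141 CPM (1.36, 1.23 to 1.49) were among the largest ratios. Egr2 (18.7 and 76.9 CPM, 2.04) and Egr3 (23.5 and 68.1 CPM, 1.54), early response transcription factors, were also higher, with the feedback inhibitor Errfi1 (205 and 518 CPM, 1.34), the matrix glycoprotein Efemp1 (103 and 270.4 CPM, 1.40), the carboxylesterase Ces1d (24.98 and 70.7 CPM, 1.501) and Ahsg (55.1 and 136 CPM, 1.30). Elastin (Eln, ENSMUSG00000029675) stood at 1008 and 251 CPM (-2.01, -2.09 to -1.93) and Angptl7 at 111 and 28.2 CPM (-1.97, -2.22 to -1.73). Other genes with lower CPM were Has1 (75.3 and 17.1 CPM, -2.14), Sfrp4 (63.1 and 16.5 CPM, -1.94), the crosslinking enzyme Lox (93.2 and 27.8 CPM, -1.74), Cilp (124 and 36.9 CPM, -1.74), Col12a1 (51.6 and 16.9 CPM, -1.61) and Cxcl13 (82.4 and 24.2 CPM, -1.76), the last from 104 and 15 cells. Cluster 28, led by Sfrp4 and Lox with Eln among its top genes, held 123 fibroblasts at 2 months and 1 at 18 months. Eln kept a ratio between -2.41 and -1.09 in every setting, whereas Has1 and Cxcl13 turned positive under the authors' filter (0.36 and 1.44) and Cilp under 5 settings. In cells with Xist and without Y-linked UMIs Has1, Sfrp4 and Cxcl13 turned to 0.52, 1.51 and 1.48. The extracellular matrix list median was -0.35 (-0.37 to -0.33) with 11 of 39 members lower, -0.35 after background subtraction, and -0.43 to -0.09 over the settings. Complement genes had a median of 0.40 (0.35 to 0.52) and type I interferon-stimulated genes 0.28 (0.18 to 0.36), with 8 of 31 members higher. Complement turned to -0.02 between Hashtag09 and Hashtag11, a pair of only 119 and 26 fibroblasts, and the type I list to -0.15 in cells with Y-linked UMIs and without Xist. The MHC class I list stood at 0.30 (0.23 to 0.37) and dissociation stress at -0.26 (-0.30 to -0.24).

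In vascular endothelial cells (2700 and 2285 cells), the IFN-γ list median was lower in the 18-month library, although by the fold rule 6 of its 36 members were higher and 4 lower. Of 32 type I interferon-stimulated genes, 3 were higher and 1 lower by that rule. Below 1.5-fold, Gbp4 stood at 289 and 200.03 CPM (-0.53, -0.63 to -0.43), Isg15 at 186 and 132 CPM (-0.49, -0.62 to -0.36) and Irf1 at 179 and 146 CPM (-0.29, -0.42 to -0.17). Bst2 (558 and 480.3 CPM, -0.22) and Gbp2 (109 and 94.7 CPM, -0.20) were slightly lower, while the chemokine Cxcl9 (77.6 and 73.3 CPM, -0.08), Ifngr1 (241 and 239.9 CPM, 0.00) and H2-D1 (1469 and 1542 CPM, 0.07) differed little. B2m (1685 and 1833 CPM, 0.12) and H2-K1 (1232 and 1398 CPM, 0.18) were slightly higher, as was Ifngr2 (40.3 and 49.8 CPM, 0.30). Among genes that the naming rule admits, the largest ratio belonged to Csprs (ENSMUSG00000062783), at 12.0 and 69.5 CPM (2.53, 2.20 to 2.88). Nr4a1, an immediate early nuclear receptor, stood at 98.4 and 234 CPM (1.248, 1.12 to 1.38), and Egr1 at 214 and 430.4 CPM (1.01, 0.92 to 1.10). Apold1, an endothelial early response gene, was at 159 and 333 CPM (1.07, 0.96 to 1.17). Sik1 (52.9 and 118 CPM, 1.16), the clock gene Per1 (45.4 and 100.2 CPM, 1.14), Lnx1 (26.0 and 54.7 CPM, 1.07) and Prg4 (44.3 and 90.8 CPM, 1.04) were higher as well. Of genes for heat shock proteins, the naming rule gave Hsph1 at 189 and 80.2 CPM (-1.24, -1.39 to -1.09), Hsp90aa1 at 778 and 465 CPM (-0.74, -0.81 to -0.68) and Hspa4l (99.8 and 55.03 CPM, -0.86), all lower. So were the apelin receptor Aplnr at 336 and 172 CPM (-0.96, -1.07 to -0.86), the retinoic acid hydroxylase Cyp26b1 (84.3 and 38.4 CPM, -1.14), Sox4 (159.5 and 84.5 CPM, -0.92) and the vascular collagen Col15a1 (147 and 77.9 CPM, -0.91). Egr1 (-0.11) and Cyp26b1 (0.57) turned in cells with Xist and without Y-linked UMIs, and Gbp2 (-0.47 to 0.19), B2m, H2-K1 and H2-D1 changed sign over the settings, whereas Gbp4 stayed between -0.94 and -0.28 in all settings. Transcripts of near-identical genes (Csprs copies, Hspa1a and Hspa1b, Ifi205 and Ifi207, H2-K1 and H2-D1, the Gbp family) are hard to tell apart, so which copy differed is uncertain. Mitochondrially encoded oxidative phosphorylation genes had a median of 0.17 (0.16 to 0.19), nuclear ones -0.19 (-0.21 to -0.16) and the dissociation stress list -0.22 (-0.33 to -0.10), which turned positive in 4 settings (0.01 to 0.50).

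Macrophages (532 and 651 cells) had higher Cxcl10, an IFN-γ-induced chemokine, at 105 and 191 CPM (0.86, 0.70 to 1.02), and higher Ifngr1 (344 and 424 CPM, 0.30). MHC class II genes H2-Aa (7557 and 8981 CPM, 0.25) and H2-Ab1 (6393 and 7369 CPM, 0.21) were slightly higher and their transactivator Ciita (197 and 156 CPM, -0.34) and Bst2 (391 and 338 CPM, -0.21) lower, while Cd74 (24657 and 25903 CPM, 0.07) differed little. H2-M2 stood at 3.22 and 70.0 CPM (4.44, 3.68 to 5.33), from 5 and 62 cells. Gdf3 (9.66 and 53.7 CPM, 2.48) and Acp5 (12.4 and 57.8 CPM, 2.22) were also higher, and so were Cd209f (5.52 and 73.5 CPM, 3.73), Ccl8 (8.05 and 80.8 CPM, 3.33) and Cxcl13 (108 and 947 CPM, 3.14), in each of which 5 cells held over 50% of the UMIs. Timd4, a phosphatidylserine receptor of resident macrophages, was lower at 51.1 and 22.7 CPM (-1.17, -1.49 to -0.86), with Adam33 (57.5 and 19.7 CPM, -1.54), Plxdc2 (69.2 and 34.7 CPM, -0.998), Cenpa (65.1 and 35.2 CPM, -0.89) and the co-chaperones Dnajb1 (205 and 95.8 CPM, -1.10) and Dnaja1 (841 and 456 CPM, -0.88). Cxcl10 turned to -0.57 between Hashtag09 and Hashtag12, so its direction differed between hashtagged subsets, and H2-Aa, H2-Ab1, Cd74 and Bst2 also changed sign in some settings.

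B cells (940 and 995 cells) had more Ciita, the class II transactivator, at 86.4 and 187 CPM (1.11, 0.97 to 1.249). Cd74 (13343 and 16863 CPM, 0.34), H2-Ab1 (2613 and 3282 CPM, 0.33) and H2-Aa (3405 and 4054 CPM, 0.25) went little beyond the B cell TMM shift of 0.24, and the class II list median of 0.33 lay within the range of random lists. Gbp2 (22.5 and 10.6 CPM, -1.09) and Bst2 (86.1 and 65.0 CPM, -0.40) were lower. Higher genes by the naming rule were Wfdc17 (12.5 and 50.5 CPM, 2.01), Treml2 (19.2 and 74.4 CPM, 1.95), Hspa1b (276 and 992 CPM, 1.85), Epb41 (20.6 and 73.7 CPM, 1.84) and Abca1 (16.9 and 60.3 CPM, 1.83). S100a6 at 1989 and 359.5 CPM (-2.47, -2.54 to -2.40) and Ccnd2 at 404 and 81.2 CPM (-2.32, -2.47 to -2.17) were lower, with Cfp (84.9 and 14.9 CPM, -2.51) and Ass1 (104 and 25.1 CPM, -2.06). Jchain (633 and 8.28 CPM, -6.26) came almost wholly from 5 cells, which held 96.1% of its UMIs. The Mzb1-led cluster 11 held 45.9% and 7.84% of B cells, and S100a6, Cfp and Ass1 turned positive in both hashtag pairs with Hashtag10. Treml2 (-0.30) and Hspa1b (-0.61) turned negative in cells with Xist and without Y-linked UMIs. TMM put the B cell shift at 0.24 log2, the largest of any class, with -0.18 in neutrophils, 0.11 in cardiomyocytes, 0.12 in pericytes and -0.13 in ILC2.

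Neutrophils (209 and 912 cells) had higher Gbp2 at 18.7 and 62.9 CPM (1.75, 1.09 to 2.49), from 15 and 77 cells, and higher Stfa2l1 (394 and 1196 CPM, 1.60), Wfdc17 (339 and 807 CPM, 1.251), Sirpb1c (101 and 238 CPM, 1.23) and Tgm2 (43.9 and 101 CPM, 1.20). H2-D1 (3195 and 3864 CPM, 0.27), B2m (1072 and 1263 CPM, 0.24), Ifngr1 (116 and 161 CPM, 0.47) and Irf1 (178 and 209.7 CPM, 0.24) were slightly higher and Isg15 (483 and 369 CPM, -0.39) lower, but over the settings Isg15 ran -1.19 to 2.18, and H2-D1 and B2m also changed sign. Among genes that passed the naming and background limits, the lowest ratios were those of Ltf (-3.18), Mgst2 (-3.10), Ngp (-3.10), Camp (-2.88) and Itgb2l (-2.84). Cluster 35, led by Ngp, Ltf and Camp, held 18.2% and 1.21% of neutrophils. The setting with equal cluster weights left it out for its 11 cells at 18 months. In the remaining cluster 3, Ltf, Ngp and Itgb2l turned (0.05 to 0.09). In smooth muscle cells (769 and 149 cells), H2-D1 stood at 128 and 248 CPM (0.96, 0.77 to 1.14), H2-K1 at 118 and 200.1 CPM (0.77, 0.57 to 0.97) and Irf1 at 39.5 and 69.8 CPM (0.82, 0.47 to 1.16), with B2m (129 and 184 CPM, 0.51). Kcna2 (16.2 and 63.3 CPM, 1.97), Sbspon (18.1 and 69.1 CPM, 1.93) and Gstt1 (19.1 and 50.2 CPM, 1.39) were higher, and Hsph1 (126 and 61.8 CPM, -1.02), Dnajb4 (293 and 149 CPM, -0.97) and Hspa1a (2281 and 1270.2 CPM, -0.84) lower. The MHC class I list median of smooth muscle cells was 0.54 (0.34 to 0.72), the highest of any class. Remaining cardiomyocytes (685 and 142 cells) had higher Tesc (26.3 and 101 CPM, 1.95) and Gstp1 (77.5 and 158 CPM, 1.03) and lower Ubl7 (50.2 and 14.2 CPM, -1.82), and mitochondrially encoded genes at 0.68 (0.62 to 0.71), with 13 of 13 members higher.

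Heart T cells (298 and 344 cells) had a higher effector list median in the 18-month library, although its members Xcl1 and Ifng were lower. Gzmk (ENSMUSG00000042385), a granzyme of effector memory CD8 T cells, stood at 7.61 and 69.5 CPM (3.19, 2.45 to 4.03), from 4 and 49 cells. Gzma was at 8.08 and 251 CPM (4.95, 4.26 to 5.74), with 73.9% of its UMIs in 5 cells. Ifng stood at 108 and 87.3 CPM (-0.31, -0.59 to -0.03), with ratios of -0.84 to 0.60 over the settings, Ifngr1 at 421 and 540.4 CPM (0.36, 0.23 to 0.48) and Ifngr2 (51.8 and 33.5 CPM, -0.63). The γδ T cell gene Cd163l1 was at 40.4 and 158 CPM (1.97, 1.62 to 2.33), and Dntt (6.66 and 66.5 CPM, 3.32), Hist1h2ap (12.4 and 58.1 CPM, 2.23) and Cd24a (16.2 and 64.0 CPM, 1.99) were higher. Lower genes were Izumo1r (52.8 and 15.3 CPM, -1.79), Xcl1 (351 and 132 CPM, -1.41), Atp1b1 (80.3 and 33.1 CPM, -1.28), Rrad (62.3 and 27.6 CPM, -1.18), Neurl3 (291 and 129 CPM, -1.17) and Dapl1 (213 and 97.9 CPM, -1.12). Of these, Xcl1 was, like Ccl5, a top gene of the effector cluster 18 (49.0% and 62.8% of T cells) and Dapl1 of the naive-like cluster 19 (51.0% and 37.2%). The effector list median was 0.55 (0.42 to 0.74), above all random lists, with 14 of 28 members higher and 1 lower. In T cells, its members Gzmb (20.9 and 82.7 CPM, 1.98), Eomes (16.2 and 61.9 CPM, 1.94) and Ccl5 (1657 and 5280.2 CPM, 1.67) were higher. The naive list stood at 0.08 (-0.05 to 0.16) and the exhaustion and checkpoint list at 0.09 (-0.06 to 0.32). Gzmk UMIs were found in 1.34% and 14.2% of T cells, or 0.678% and 5.93% after thinning to 1000 UMIs. Smooth muscle cells, which should lack them, had 0.130% and 0.671%, and after thinning 0 of 757 and 0 of 146 cells (upper limits 0.486% and 2.49%). Median depths were 6813 and 6557 UMIs in T cells and 9147 and 9195 in smooth muscle cells. Ccl5 was found in 29.5% and 46.2% of T cells (25.4% and 40.1% thinned) and in 2.47% and 9.40% of smooth muscle cells (0.132% and 1.37% thinned). Ifng was found in 21.1% and 17.2% of T cells (7.80% and 6.23% thinned) and in 0.260% and 0.671% of smooth muscle cells (0 of 757 and 0 of 146 thinned). Gzmk kept a positive ratio in every setting (1.46 to 5.50), whereas Dntt (-3.12), Hist1h2ap (-0.88), Cd24a (-2.66), Izumo1r (0.44), Rrad (0.16) and Neurl3 (0.12) turned between Hashtag10 and Hashtag12, and Xcl1 turned to 1.70 at resolution 2.

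Of the 5 highest and 5 lowest median gene ratios over heart classes, all but that of Sik1 came with an estimated background of at least 83.7% of the UMIs. Median ratios over classes were highest for Ccl5 (2.38), S100a8 (2.15), S100a9 (2.06) and Il1b (1.46), whose estimated background medians were 86.8%, 190.3%, 167% and 112% of their UMIs. Fbln1 (-2.76), Col3a1 (-2.73), Jchain (-2.64), Nppa (-2.48) and Myl7 (-2.41) were lowest, with background medians from 83.7% to 142%. Sik1, a salt-inducible kinase, had a median of 0.86 over 12 classes at a background of 5.39%, and passed the 1.5-fold rule in 5 of them. MHC class II medians ran from -1.12 (-1.29 to -0.94) in monocytes to 1.003 (0.83 to 1.22) in smooth muscle cells, where background came to 205% of the member UMIs. By this estimate, class II UMIs in T cells were mostly free RNA (78.1%, median 0.52, and -0.89 after subtraction). In vascular endothelial cells, the class II median stayed above 0 over the 22 settings that gave a value (0.23 to 1.16). Inflammatory cytokine medians ran from -0.20 (-0.38 to -0.09) in monocytes to 1.83 (1.23 to 2.00) in pericytes, and extracellular matrix medians from -2.54 (-2.74 to -2.31) in neutrophils to 0.18 (-0.09 to 0.25) in smooth muscle cells, the former above 0 in 11 and the latter in 1 of 13 classes. In endothelial cells the inflammatory median of 0.56 was -0.13 after subtraction, and the matrix median of -0.91 was 0.12. These later medians took only members with at least 20 UMIs left, so they can rest on fewer members. Cardiomyocyte genes ran from -2.31 (-2.67 to -1.62) in endocardial cells to 0.13 (-0.01 to 0.17) in cardiomyocytes, and haemoglobin genes, measured in only 2 classes, from -3.05 (-3.35 to -2.72) in fibroblasts to 5.22 (4.99 to 5.47) in vascular endothelial cells.

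Dissociation stress medians ran from -1.05 (-1.42 to -0.89) in pericytes to 0.48 (0.18 to 0.60) in cardiomyocytes, with 21 of 23 members lower in pericytes. MHC class I medians ran from -0.19 (-0.25 to -0.03) in ILC2 to 0.54 (0.34 to 0.72) in smooth muscle cells, and type I interferon-stimulated genes from -0.58 (-1.73 to 0.15) in cardiomyocytes to 0.37 (0.07 to 0.53) in smooth muscle cells. Mitochondrially encoded oxidative phosphorylation genes ran from -0.33 (-0.41 to -0.29) in neutrophils to 0.68 (0.62 to 0.71) in cardiomyocytes, and nuclear ones from -0.22 (-0.24 to -0.17) in B cells to 0.05 (0.02 to 0.06) in fibroblasts. Glycolysis genes ran from -0.26 (-0.36 to -0.15) in neutrophils to 0.15 (0.08 to 0.20) in fibroblasts, and fatty acid oxidation genes from -0.67 (-1.01 to -0.46) in neutrophils to 0.09 (-0.01 to 0.15) in cardiomyocytes. Complement medians ran from -0.45 (-0.70 to -0.13) in monocytes to 0.87 (0.55 to 1.20) in smooth muscle cells, and senescence and CDK inhibitor genes from -0.57 (-0.76 to -0.30) in dendritic cells to 0.12 (-0.04 to 0.24) in vascular endothelial cells. Cell cycle genes ran from -1.21 (-1.70 to -0.51) in monocytes to 0.59 (-0.12 to 1.13) in endocardial cells, and were lower in B cells (-0.57, -0.77 to -0.41). Ribosomal protein genes ran from -0.27 (-0.29 to -0.26) in B cells to 0.41 (0.39 to 0.45) in endocardial cells. The effector list ran from -0.25 (-0.75 to 0.26) in cardiomyocytes to 1.65 (0.80 to 1.78) in fibroblasts, where its members were mostly background (140.1%), the naive list from -0.55 (-1.05 to -0.17) in pericytes to 0.78 (0.53 to 0.92) in dendritic cells, and the exhaustion and checkpoint list from -0.87 (-1.76 to -0.24) in pericytes to 0.40 (0.13 to 0.55) in neutrophils.

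In the lymph node library, hashtag 7 stood apart by type 1 effector or memory T cells, the state with Gzmk, Ccl5 and Eomes. They made up 7.61% in hashtag 2 to 55.5% in hashtag 7, median 15.6% over the 8 hashtags. Naive or central memory cells ran from 9.14% in hashtag 7 to 36.5% in hashtag 1, median 19.1%, and regulatory T cells from 6.28% in hashtag 7 to 21.1% in hashtag 6, median 16.7%. Follicular helper T cells ran from 0.903% in hashtag 2 to 14.0% in hashtag 8, median 4.57%, and γδ T cells from 0.603% in hashtag 7 to 6.46% in hashtag 4, median 1.78%. Cycling cells (2.61% in hashtag 8 to 5.94% in hashtag 2, median 3.54%), exhausted-like cells (0.201% in hashtag 7 to 1.40% in hashtag 4, median 0.607%) and cytotoxic cells (0% in hashtag 7 to 0.567% in hashtag 5, median 0.261%) were rare. The cytotoxic cells were cluster 30 (22 cells), led by Gzma with Ncr1, Klrb1c and Klra8, which served as NK cell markers in the heart. They may thus be NK cells, and their share does not measure how common cytotoxic T cells were. B cell clusters (4.65% in hashtag 2 to 16% in hashtag 8, median 6.64%) and myeloid clusters (2.26% in hashtag 7 to 4.26% in hashtag 2, median 3.09%) were also present, and unnamed clusters held 13.9% in hashtag 7 to 21.1% in hashtag 5, median 19.1%. Among the unnamed, cluster 6 (592 cells), led by Klra7, Klrc1, Klre1 and Gzmm, scored closest to the type 1 state. It had no marker of that state among its top 10 genes, so the type 1 shares leave it out. Cluster 0 gave 1393 of the 2387 type 1 cells at a median of only 789 UMIs, led by Gzmk together with AY036118, Gm42418, Lars2 and Malat1, transcripts often seen in damaged cells. The lowest hashtag held 2.04% under the stricter filter, 1.74% under the authors' filter and 0.324% under the stricter hashtag rule, and the highest 47.5%, 47.0% and 34.6%.

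Clonal expansion was also largest in hashtags 7 and 8, but hashtags may differ in their number of animals, which alone can change these shares. Among cells with Xist or Y-linked UMIs but not both, 93.3% and 88.4% had Xist only in hashtags 7 and 8. In hashtags 1 to 6 this ran from 19.9% to 79.5%, so some of these may mix animals of both sexes. Thinned to 549 cells, expanded clonotypes held 33.5% (29.6 to 37.6) of cells in hashtag 7 and 27.3% (23.6 to 31.3) in hashtag 8. Hashtags 1 to 6 had 10.6% (8.12 to 13.4), 10.7% (8.28 to 13.6), 10.1% (7.80 to 13.04), 12.1% (9.58 to 15.2), 14.3% (11.6 to 17.6) and 17.3% (14.2 to 20.7), and the median over all 8 was 13.2%. The largest 10 clonotypes held 4.74% to 14.7% (median 6.18%). Gini indices ran from 0.0544 to 0.222 (median 0.0756), and Shannon diversity from 5.81 to 6.22 nats (median 6.18). Of 5712 clonotypes, 599 had at least 2 cells, and these held 1861 cells (26.7%). The largest clonotype, with TRBV23, had 49 cells, all in hashtag 7. The next had 31 cells (30 in hashtag 7) and 23 cells (all in hashtag 7). Of 66 clonotypes with at least 5 cells, 35 lay mainly in hashtag 7 and 19 in hashtag 8. Pairs of cells of one clonotype shared a hashtag in 95.8% of cases, against a mean of 13.8% with hashtags shuffled. Expanded cells made up 48.8% of type 1 cells with a receptor, 44.9% of cycling cells, 39.4% of follicular helper cells, 15.6% of naive or central memory cells, 17.8% of γδ cells, 14.8% of regulatory cells and 9.09% of 66 exhausted-like cells. In B and myeloid clusters they made up 30.8% of 146 and 30.5% of 82 cells with a receptor. These shares pool all hashtags, and hashtag 7 gave 1105 of the 2387 type 1 cells. Over hashtags with at least 10 such cells, shares ran from 12% to 59.0% in type 1 and 20% to 75% in cycling cells. Follicular helper cells ran from 27.5% to 47.4%, naive or central memory cells from 5.79% to 42.3% and regulatory cells from 5.71% to 23.8%. The order of the states is thus not separate from hashtag.

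**Figure D3:**
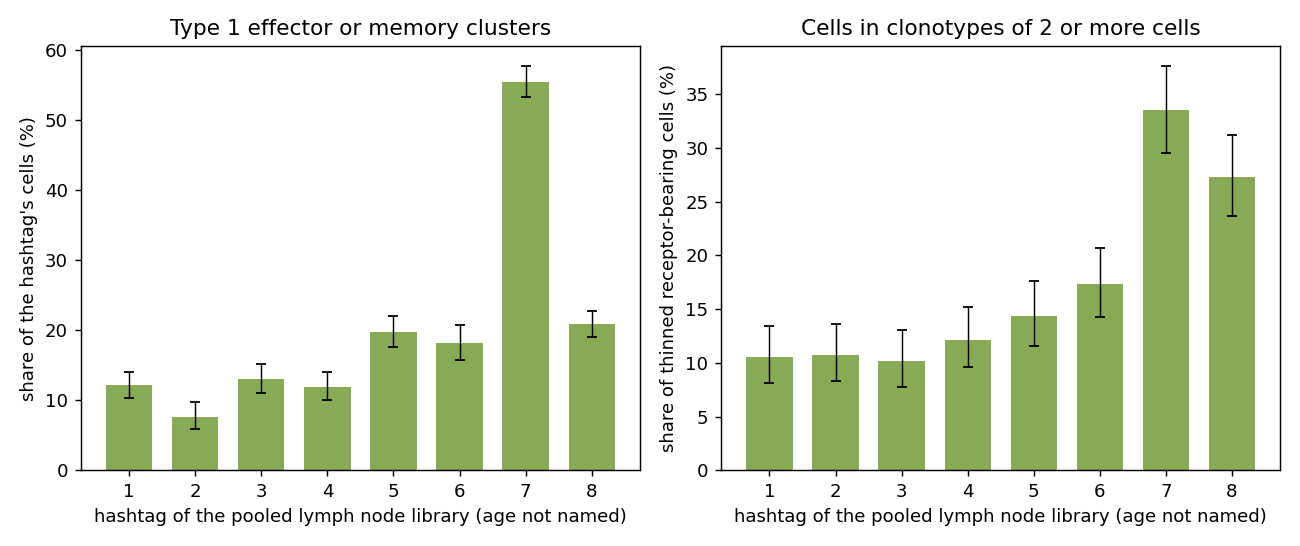
Left: percent of cells in type 1 effector or memory clusters per lymph node hashtag. Right: percent of cells in expanded clonotypes after thinning each hashtag to 549 cells, both with 95% Clopper-Pearson intervals; hashtag ages are unnamed.

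Expanded cells (1861) carried more Gzmk, Pdcd1 and Tox transcripts than single cells (5113), in each of the 8 hashtags. Gzmk stood at 743 CPM in expanded and 142 CPM in single cells (2.39, 2.33 to 2.46), higher in 8 of 8 hashtags with a median hashtag ratio of 1.97. Pdcd1, the PD-1 receptor gene, stood at 266 CPM in expanded and 131 CPM in single cells (1.02, 0.94 to 1.11), also higher in all 8 hashtags (median 1.06), as was the exhaustion-linked factor Tox (207 against 107 CPM, 0.95, median hashtag 0.71). Hist1h1b, a histone gene of dividing cells, stood at 166 CPM in expanded and 38.2 CPM in single cells (2.11, 1.98 to 2.24) and was higher in 7 hashtags. Ccl5 (11073 against 3444 CPM, 1.69, median hashtag 0.64) was higher in 6 hashtags and reached at most 1.09 in any one, so differences between hashtags added to its summed ratio. Ifng stood at 22.95 CPM in expanded and 11.3 CPM in single cells (1.02, 0.72 to 1.32), but its median hashtag ratio was -0.04, and 0.47 remained without hashtag 7. Nkg7 (1539 against 787 CPM, 0.97, median hashtag 0.22), Eomes (178 against 98.3 CPM, 0.86, median hashtag 0.03), Cxcr3 (238 against 171 CPM, 0.47, median hashtag 0.16) and Ier3 (131 against 25.9 CPM, 2.34, median hashtag 0.57) likewise differed less within hashtags. Gzmb (29.6 against 6.94 CPM, 2.09, median hashtag 1.79) was measured in 6 hashtags, and Ccl3 (60.6 against 9.39 CPM, 2.69, median hashtag 1.97) in 5. Ccl4 (265 against 55.4 CPM, 2.26, median hashtag -1.32) was lower in 5 of 8 hashtags, with 57.2% of its UMIs in 5 cells. Foxp3, the regulatory T cell factor, stood at 32.7 CPM in expanded and 75.4 CPM in single cells (-1.21, -1.42 to -0.99) and was lower in all 8 hashtags (median -0.54), as was Igfbp4 (13.4 against 62.0 CPM, -2.21, median hashtag -1.28). Dapl1 (39.0 against 135 CPM, -1.79, median hashtag -1.38), Treml2 (22.6 against 52.2 CPM, -1.21, median hashtag -0.90), Ccr7 (96.6 against 208 CPM, -1.11, median hashtag -0.65) and Lef1 (144 against 210.0 CPM, -0.55, median hashtag -0.28) were lower in 7 hashtags. Tbx21 (44.8 against 42.6 CPM, 0.07, median hashtag -0.40) and Tcf7 (275 against 269 CPM, 0.03, median hashtag -0.08) differed little in the summed ratio, and Slpi (13.05 against 101 CPM, -2.96, median hashtag -0.95) was a top gene of the plasma-like cluster 29, with 93.1% of its UMIs in 5 cells. In the exact sign-flip permutation test over hashtags, 10 of 21 genes passed an adjusted p of 0.05: Gzmk, Pdcd1, Tox, Foxp3 and Igfbp4 (0.0328 each), Hist1h1b, Treml2 and Ccr7 (0.0410 each), and Dapl1 and Lef1 (0.0492 each). The others did not (0.219 to 0.773). Of the passing genes, Hist1h1b, Igfbp4, Dapl1 and Treml2 were tested only because their summed ratios in these same cells were extreme. Their results are therefore no separate support, while the rest were fixed by name beforehand. No gene passed with cells thinned to 1000 UMIs or within type 1 clusters, where the means over hashtags turned to -0.72 for Gzmk and -0.03 for Tox. Since Gzmk is among the markers that named these clusters, its ratio within them is limited by construction.

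The effector list median of expanded over single cells was 0.66 (0.55 to 0.84), above all random lists, with 16 of 29 members higher. Per hashtag it ran from -0.61 to 0.56 with a median of 0.05, and at equal hashtag weights it was 0.43. Within type 1 clusters it was 0.11, but effector genes such as Gzmk and Ccl5 helped to name these clusters, which can lower it by construction. The exact sign-flip permutation test over the 8 hashtags did not pass (mean 0.02, above 0 in 5, adjusted p 0.933). The exhaustion and checkpoint list stood at 0.69 (0.52 to 0.77), the MHC class II list at 0.65 (0.36 to 0.73), the cell cycle list at 0.58 (0.44 to 0.63) and the naive list at -0.52 (-0.60 to -0.45). Their median hashtag values were 0.60, 0.13, 0.35 and -0.37. The class II list ran from -1.01 to 2.54 over hashtags and did not pass the exact sign-flip permutation test (adjusted p 0.490). The expanded cells included 45 of B and 25 of myeloid clusters, so it need not be a trait of T cells. The IFN-γ response list was lower at -0.24 (-0.30 to -0.18), below 0 in all 8 hashtags, and type I interferon-stimulated genes stood at -0.33 (-0.43 to -0.22), above 0 in 3. By rank among random lists, MHC class I (0.16) and fatty acid oxidation genes (0.18) were higher, and dissociation stress (-0.23), mitochondrially encoded (-0.11) and ribosomal protein genes (-0.18) lower. Glycolysis (0.16), inflammatory (0.16), complement (0.14), senescence (0.13) and nuclear oxidative phosphorylation genes (0.06) lay within the range of random lists. The sign-flip test passed an adjusted p of 0.05 in 6 of 16 lists: the IFN-γ, naive and mitochondrially encoded lists, below 0 in all 8 hashtags, the nuclear list, above 0 in all 8 (adjusted p 0.0313 each), and the cell cycle and ribosomal lists, above and below 0 in 7 (0.0417). The exhaustion and checkpoint list missed it (0.0938), as it did in 10 of 12 other settings, and passed in 2. No list passed within CD4 cells, within type 1 clusters or under the stricter hashtag rule, and 3 passed with TMM factors, where the nuclear mean of 0.10 over hashtags turned to -0.03. With 7 hashtags, as without hashtag 7 or with expansion at 5 cells, no list or gene passed either, at a smallest p of 0.0156. Gzmk was found in 41.6% of expanded and 14.7% of single cells (33.3% of expanded and 9.83% of single cells after thinning), against 2.92% (2.45%) of B cluster cells. Pdcd1 was found in 32.8% of expanded and 24.4% of single cells (19.3% of expanded and 12.1% of single cells after thinning), against 1.253% (0.524%). Median depths were 2526, 3864 and 2705 UMIs in expanded, single and B cluster cells.

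**Figure D4:**
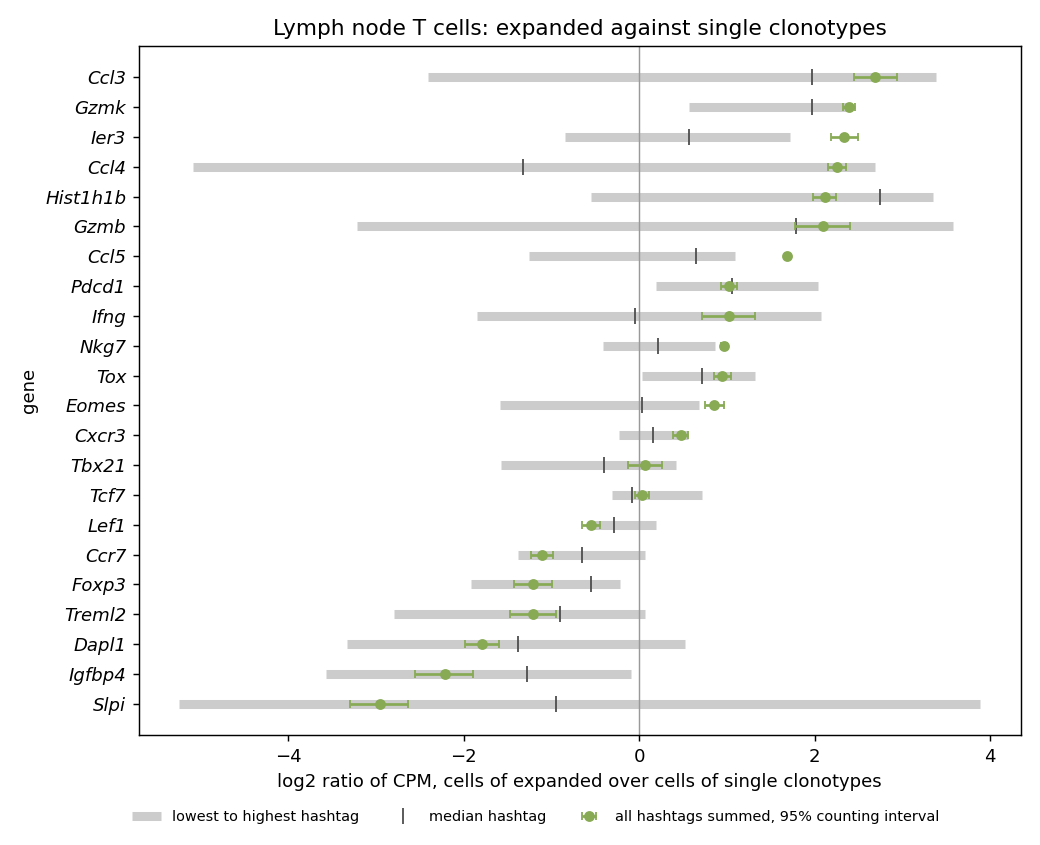
Log2 CPM ratio of expanded over single cells for 22 genes in the lymph node library: points with 95% counting intervals for the summed cells, grey bars from the lowest to the highest hashtag, ticks at the median hashtag. Gzmk, Pdcd1 and Tox were higher, and Foxp3 and Igfbp4 lower, in all 8 hashtags.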

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

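All tests in this part but the sign-flip test were chosen after the results had been seen. Hashtag antibody signal appeared in the heart libraries, whose labels use no hashtag: 38.0% of 2-month cells and 67.3% of 18-month cells carried one. Hashtag09 and Hashtag10 were in the 2-month library, and Hashtag11 and Hashtag12 in the 18-month library. Of macrophages, neutrophils, monocytes, dendritic, B and T cells and ILC2, 90.4% to 100% of each class carried one, against 6.99% and 10.0% of fibroblasts and 30.5% and 47.8% of endothelial cells. The source of the hashtagged cells is not given in the sources used here, and this difference between libraries was not tested.

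The first pattern weighed was the higher IFN-γ list median in fibroblasts of the 18-month library (main value 0.35). If deeper cells or free RNA made the whole difference, thinning or background subtraction should have taken it to 0, but it was 0.39 (0.04 to 0.56) over 20 thinnings, which alone ranged from 0.08 to 0.60, and 0.35 (0.22 to 0.44) after subtraction. If animals of one sex carried it, a split by sex transcripts should have left it on one side only: it was 0.47 (0.31 to 0.64) in cells with Xist and 0.075 (-0.18 to 0.14) in cells with Y-linked UMIs. Free RNA is thus unlikely to be the whole cause. The sums of the 20 thinnings were averaged, which gives back much of the depth taken away. With the wide interval, they cannot decide on a part from depth (medians of 12506 and 11248.5 UMIs per cell). A difference limited to cells with Xist remains possible. Age remains a biological explanation that 1 library per age could not test.

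The second pattern was the higher effector list median in heart T cells of the 18-month library (main value 0.55). Equal weights of the T cell clusters gave 0.26 (0.14 to 0.40). Effector genes such as Ccl5 and Nkg7, top genes of cluster 18, were not kept out of the clustering. Equal weights can thus lower the median by construction and cannot decide what a shift between the clusters accounts for. Whether NK cells within the clusters added to the higher median is open. The median was 0.65 (0.56 to 0.89) in the 284 and 337 cells with a Cd3 UMI. These were nearly all of the 298 and 344 cells, and no NK cell marker was used, so this could not decide it. Whether a few very rich cells made it was not tested. A biological shift of heart T cells towards effector states may remain, and its tie to age was not tested.

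The third pattern was the higher effector list median in expanded lymph node cells (main value 0.66). By cluster, 15 of the 31 clusters gave 0.51 (0.46 to 0.78) at their own weights and 0.20 (0.16 to 0.37) at equal weights. Effector genes were not kept out of the clustering, and some of them named the type 1 clusters. Equal weights can thus lower the median by construction and cannot decide what cluster makeup explains. How much hashtag makeup explains is open: equal hashtag weights gave 0.43 (0.28 to 0.53), but the medians of single hashtags had a mean of only 0.017 (sign-flip permutation p 0.875, above 0 in 5 of 8). The largest 10 clonotypes explained little, at 0.64 (0.53 to 0.70) without them. No biological explanation was tested.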

How the results depend on the processing

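The splits by heart hashtag and sex transcript, background subtraction, equal cluster or hashtag weights, T cells with a Cd3 UMI, the authors' filter, and for the lymph node leaving out hashtag 7 or B and myeloid clusters, type 1 clusters alone and other scaling, were chosen after the data were seen. The rest were planned. Of 17 heart share ratios, all kept their sign in every setting, with 105 of 115 values within the counting interval. Fibroblast share ratios ran -1.96 to -1.82 and neutrophil ratios 2.55 to 2.73. Of 129 heart gene ratios past the 1.5-fold rule and chosen for the text, 98 kept their sign everywhere (2478 values: 1705 unchanged, 721 moved, 52 turned). Among all 414 such ratios of genes by class, before the limits on background and rich cells, 295 kept their sign and 119 turned in some setting. Of 46 heart list medians beyond random lists, 32 kept their sign (894 values: 607 unchanged, 260 moved, 27 turned). In the lymph node, 16 of 18 gene ratios and all 7 list medians kept their sign. Endothelial Csprs stayed at 1.86 to 3.49, Hsph1 at -1.84 to -0.79 and Aplnr at -1.247 to -0.63, fibroblast Ifi207 at 1.39 to 2.62, and lymph node Gzmk at 0.38 to 3.01, Pdcd1 at 0.45 to 1.84 and Foxp3 at -2.72 to -0.61. Of 16 lists and genes that passed the sign-flip test, 104 of 202 values still passed, 92 fell short and 6 turned. Median depths were 2288.5 and 2322 UMIs in endothelial cells, 12506 and 11248.5 in fibroblasts and 8979.5 and 4349 in B cells, and what depth limits was not measured apart from class size. At the depths and cell numbers found, 79.7% (T cells) to 90.6% (endothelial cells) of simulated 2-fold changes passed the fold rule.

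Of values short of these rules, 21 of 35 heart gene ratios and 22 of 25 heart list medians changed sign in some setting, and are not listed here. The values that turned among those past the rules, and the moved values of the main results, follow by setting as log2 ratios or list medians unless in percent. Apart from the smaller number of hashtags given below, the cause was not tested. Fibroblast values between hashtags rest on few cells: 119 with Hashtag09 and 46 with Hashtag10, each against 26 with Hashtag11. Between Hashtag09 and Hashtag11: fibroblast IFN-γ list 0.53 and complement list -0.017, macrophage IFN-γ list -0.065, MHC class I list -0.075, MHC class II list -0.048, Cxcl10 -0.059, Cxcl13 -0.024 and Cenpa 0.044, neutrophil IFN-γ list -0.43, T cell MHC class II list -0.22, dendritic naive list -0.044. Between Hashtag09 and Hashtag12: endothelial IFN-γ list -0.088 and Cyp26b1 0.81, macrophage MHC class II list -0.017 and Cxcl10 -0.57, T cell Cd24a -2.36, ILC2 Ccl1 -0.078. Between Hashtag10 and Hashtag11: fibroblast IFN-γ list 0.13 and Irf1 0.013, endothelial IFN-γ list -0.61 and dissociation stress list 0.50, B cell IFN-γ list -0.22, Treml2 -0.21, Cfp 1.73, S100a6 1.98, Ccnd2 0.45, Ass1 0.43 and ribosomal list 0.061, T cell Izumo1r 0.38 and Rrad 0.16, monocyte Lyz1 2.38, inflammatory list 0.081 and complement list 0.65. Between Hashtag10 and Hashtag12: endothelial IFN-γ list -0.48 and dissociation stress list 0.26, B cell IFN-γ list -0.020, Hspa1b -0.16, Cfp 0.57, S100a6 0.96, Ass1 0.11 and ribosomal list 0.031, macrophage IFN-γ list 0.19, T cell Dntt -3.12, Hist1h2ap -0.88, Cd24a -2.66, Izumo1r 0.44, Rrad 0.16 and Neurl3 0.12, dendritic Cxcl9 -0.69 and Il4i1 1.91, monocyte Lyz1 3.05 and complement list 0.15, ILC2 Ccl1 -1.65. In cells with Xist and without Y-linked UMIs: fibroblast IFN-γ list 0.41, Has1 0.52, Sfrp4 1.51 and Cxcl13 1.48, B cell IFN-γ list -0.041, Treml2 -0.30, Hspa1b -0.61, S100a6 0.58, Ass1 1.19 and ribosomal list 0.028, macrophage IFN-γ list 0.40, endothelial Egr1 -0.11 and Cyp26b1 0.57, T cell Izumo1r 0.20, monocyte inflammatory list 0.089. In cells with Y-linked UMIs and without Xist: fibroblast IFN-γ list 0.066 and type I interferon list -0.15, endothelial IFN-γ list -0.37 and dissociation stress list 0.23, B cell IFN-γ list 0.015, macrophage IFN-γ list -0.14, smooth muscle type I interferon list -0.065. In cells without a hashtag: endothelial IFN-γ list -0.28 and dissociation stress list 0.013. With cells thinned to 1000 UMIs: fibroblast IFN-γ list 0.062, B cell IFN-γ list -0.10, macrophage IFN-γ list 0.32, neutrophil IFN-γ list -0.11, lymph node expanded over single effector list 0.42, sign-flip test genes passing 0. Under the authors' filter: endothelial share ratio 0.047, macrophage IFN-γ list 0.20, lymph node type 1 lowest hashtag share 1.74% and highest hashtag share 47.0%, lymph node expanded over single Slpi 0.69, fibroblast Has1 0.36 and Cxcl13 1.44, B cell Jchain 1.73, dendritic senescence list 0.050, lymph node mean over hashtags effector list -0.016. Under the stricter filter (500 genes, 5% mitochondrial UMIs): endothelial share ratio 0.078, lymph node type 1 lowest hashtag share 2.04% and highest hashtag share 47.5%, fibroblast Cilp 0.19. With TMM factors: B cell IFN-γ list -0.056, sign-flip test lists passing 3, lymph node mean over hashtags nuclear oxidative phosphorylation list -0.026 and effector list -0.11. With median-of-ratios factors: B cell IFN-γ list -0.045, sign-flip test lists passing 3, lymph node mean over hashtags nuclear oxidative phosphorylation list -0.019 and effector list -0.11. At equal cluster weights (neutrophils without cluster 35): B cell IFN-γ list 0.021, neutrophil IFN-γ list -0.085, Ltf 0.047, Ngp 0.087 and Itgb2l 0.047. With interferon and MHC genes kept in the clustering: macrophage IFN-γ list 0.26, fibroblast Cilp 0.081. As a mean of CPM per cell: neutrophil IFN-γ list -0.053. After background subtraction: T cell MHC class II list -0.89. With doublets kept: fibroblast Cilp 0.13, smooth muscle type I interferon list -0.092. At resolution 0.5: fibroblast Cilp 0.076. At resolution 2: fibroblast Cilp 0.024, T cell Xcl1 1.70. With no filter on cells: pericyte naive list 0.032. With the stricter hashtag rule (20 UMIs, 10 times the second): lymph node type 1 lowest hashtag share 0.324% and highest hashtag share 34.6%, lymph node expanded-cell lowest hashtag share 6.71%, sign-flip test lists passing 0. With clonotypes by TRB sequence: lymph node expanded-cell lowest hashtag share 16.2% and highest hashtag share 47.0%. With expansion at 3 cells: lymph node expanded-cell lowest hashtag share 2.88% and highest hashtag share 22.7%. With expansion at 5 cells (also 7 hashtags): sign-flip test lists passing 0 and genes passing 0, lymph node mean over hashtags effector list -0.065. Without the largest 10 clonotypes: lymph node mean over hashtags effector list -0.023. Without hashtag 7 (smallest p 0.0156 with 7 hashtags, while the means over hashtags were still -0.34 for the naive list, -0.24 for the IFN-γ list, 1.77 for Gzmk and 1.13 for Pdcd1): sign-flip test lists passing 0 and genes passing 0, lymph node mean over hashtags effector list -0.061. Without thinning of cells: lymph node expanded-cell highest hashtag share 44.0%. Within CD4 cells: lymph node expanded over single effector list 0.42 and Ifng -0.12, sign-flip test lists passing 0 and genes passing 3, lymph node mean over hashtags cell cycle list -0.053. Within CD8 cells: lymph node expanded over single Slpi 0.85, sign-flip test lists passing 3 and genes passing 6. At equal hashtag weights: lymph node expanded over single effector list 0.43. Within type 1 clusters: lymph node expanded over single effector list 0.11 and Slpi 0.013, sign-flip test lists passing 0 and genes passing 0, lymph node mean over hashtags effector list -0.60, ribosomal list 0.00667, Gzmk -0.72 and Tox -0.025.

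Leaving out each hashtag in turn, and edgeR and DESeq2 tests with or without a filter on low counts, were planned only for hashtags of named ages and were not run, so of the hashtags only 7 was left out. Settings that left too few cells in a class gave no value there.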

Other observations

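No test was run in this part, and its values were chosen by the naming rule or after the results had been seen. Endocardial cells (142 and 228 cells) had Npr3, the natriuretic peptide clearance receptor, at 14.6 and 978 CPM (6.07, 5.18 to 7.13), from 6 and 82 cells. Npr3 is also a marker used to name this class, whose cluster was led by Vwf and Plvap, so whether it held the same kind of cell in both libraries is open. Smoc1 (1.46 and 92.7 CPM, 5.99) and Plagl1 (4.37 and 229 CPM, 5.71) rested on 1 and 3 UMIs at 2 months, and the matrix genes Hapln1 (290.0 and 43.7 CPM, -2.73) and Vcan (99.1 and 15.2 CPM, -2.71) and the sterol enzyme Fdps (80.1 and 12.5 CPM, -2.68) were lower in the 18-month library. Pericytes (205 and 51 cells) had lower Fos, an immediate early gene, at 1127 and 163 CPM (-2.79, -3.22 to -2.39), with Fosb (342 and 51.2 CPM, -2.74) and Rasl11b (56.7 and 12.8 CPM, -2.15), and higher Col8a1 (21.1 and 83.2 CPM, 1.98), Pde4c (35.6 and 102 CPM, 1.52) and Slc8b1 (22.5 and 64.0 CPM, 1.51). Monocytes (63 and 310 cells) had lower class II genes H2-Ab1 (3528 and 1007 CPM, -1.81) and H2-Aa (3802 and 1200.4 CPM, -1.66) and higher Cd244 (16.7 and 106 CPM, 2.67) and Hes1 (14.3 and 90.5 CPM, 2.66). The Cd300e-led cluster 27 held 12.7% and 46.5% of monocytes. Lyz1 (930.3 and 79.6 CPM, -3.55), Ccl4 (637 and 107 CPM, -2.58) and Celf4 (67.9 and 13.4 CPM, -2.34) each had over 50% of their UMIs in 5 cells.

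Dendritic cells (307 and 270 cells) had lower Ptgs2, the inducible prostaglandin synthase, at 119 and 26.5 CPM (-2.16, -2.45 to -1.89), with Sdc4 (147 and 36.4 CPM, -2.01) and Il4i1 (81.9 and 17.2 CPM, -2.25). The Xcr1-led cluster 29, with Itgae among its top genes, held 10.1% and 26.3% of dendritic cells, and the Cxcl9 ratio (11.7 and 81.4 CPM, 2.80) came from 5 cells holding 98.2% of its UMIs. ILC2 (80 and 108 cells) had higher Nkg7 (12.5 and 106 CPM, 3.09), from 4 and 25 cells, and Ramp3 (19.6 and 148 CPM, 2.92), and lower Gadd45g (99.9 and 23.4 CPM, -2.10), Hilpda (186 and 58.4 CPM, -1.67) and Msl2 (64.2 and 22.2 CPM, -1.53). In Ccl1 (78.5 and 394 CPM, 2.33) and in cardiomyocyte Neurl3 (10.4 and 76.9 CPM, 2.88), 5 cells held over 90% of the UMIs.

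Among heart cells with Xist or Y-linked UMIs but not both, 40.3% and 45.2% had Xist only in the 2-month and 18-month libraries. These shares were 9.08% and 26.9% in B cells, 56.9% and 17.7% in neutrophils, 21.3% and 52.1% in T cells, 47.0% and 88% in ILC2, 19.2% and 49.8% in dendritic cells, 38.4% and 43.5% in fibroblasts, 67.8% and 47.7% in smooth muscle cells and 59.9% and 57.4% in endothelial cells, so both sexes were present in each library and the mix differed by class. In the lymph node, hashtags 1 to 8 had 51.6%, 19.9%, 66.3%, 44.3%, 46.6%, 79.5%, 93.3% and 88.4%.

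Over the cells with a receptor in each lymph node hashtag, Gzmk ran from 14.6 in hashtag 2 to 955 CPM in hashtag 7, median 95.6, Ccl5 from 931 in hashtag 2 to 12133 CPM in hashtag 7, median 3012, and Eomes from 69.7 in hashtag 3 to 237 CPM in hashtag 7, median 88.8. Ifng ran from 6.77 in hashtag 1 to 20.4 CPM in hashtag 7, median 12.5, Pdcd1 from 69.7 in hashtag 1 to 285 CPM in hashtag 8, median 136, and Tox from 75.5 in hashtag 1 to 194 CPM in hashtag 7, median 107. Nkg7 ran from 568 in hashtag 1 to 1621 CPM in hashtag 7, median 769, and Foxp3 from 40.0 in hashtag 7 to 91.0 CPM in hashtag 6, median 69.9. Ccr7 ran from 112 in hashtag 7 to 278 CPM in hashtag 1, median 202. No age was inferred for any hashtag.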
